A study of Mus musculus with 82 samples.

How the data were processed

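RNA was sequenced from punches of the right ear of female C57BL/6J mice, stored in RNAlater, extracted with TRI reagent and made into libraries with the Tecan Universal Plus mRNA kit from 1 µg of total RNA, per the labels' protocols. The sham group is called vehicle in one label and sham in the sample titles, and it is called sham here. The deposited tables hold estimated counts per gene, summed from salmon according to the names of the deposited tables and made against the GRCm39 build per the submitters' processing notes. The version of salmon, the annotation release, the strand setting, read trimming and any filter are not given in the sources used here. Both tables list 56941 genes, some of their values are fractional, and column totals differ between samples, so they were read as counts that had not been scaled to depth. Every column was matched to a sample by its title, with 0 columns left over, and all 82 libraries were used. No pair of libraries in a group was closer than independent libraries should be (lowest chi-square per gene 4.55), so none looked like a copy of another.

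Counts were rounded to whole numbers. Depth was 13.1 M to 35.4 M counts in the time course, with 22835 to 26381 genes detected per library, and 24.1 M to 35.5 M in the start-day experiment, with 24438 to 26107. A gene with 3 counts per library is therefore near 0.1 to 0.2 CPM, where counting error alone is large, and sham ears held few counts of Il17a, Il22 and Ccr6. The 2 experiments were fitted apart with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr on group, scaled by TMM factors, and tested by the robust quasi-likelihood F test with 1 coefficient for each group and all groups of the experiment in 1 fit. P values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was called. Comparisons, gene lists, the naming of genes and the alternatives named below were fixed before the data were examined, except where the text says otherwise and except the differences of set medians between days and start days and the joint fit, which were added later. Differences of effects among days were tested by F tests on the contrasts of contrasts. Drug groups were compared with the imiquimod group of the same experiment, and the 3 start-day comparisons therefore share their imiquimod libraries, so overlaps among them were not computed.

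Log2 CPM for medians, figures and principal components used a prior count of 2. For sets of imiquimod genes, the genes were chosen in the other experiment (adjusted p under 0.05 and a log2 fold change of at least 1 in size), and the median difference between drug and imiquimod libraries was tested by exact permutation over all 924 relabellings, two-sided, with a jackknife standard error. Differences of these medians between days used permutation of days within treatment (1e+05 draws), with 10 tests adjusted together. The 34 gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data and with fry. A joint edgeR fit of both experiments tested whether the effects at day 8 and from day 0 differed. DESeq2 1.42.0 served as the other count test, and figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

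Genes were named by a fixed rule: 12 panel genes with values whether or not they passed, the 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of at least 1 (gene models without a family name left out), up to 4 called members of a described list by smallest adjusted p, and the 10 smallest adjusted p of an F test. Some genes that this rule would name are not reported here. Where a group held 0 counts, the fold change was bounded with 3 counts in its place, and where it held 1 to 3 counts a 95% interval of the ratio was computed from the counts.

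The edgeR step was tested on simulated data with known changes in 50 genes at each size. Only genes above a minimum expected count were changed, genes were simulated independently, and only the compared groups were fitted. The shares below may not hold for genes with few counts or for the fit of all groups. At the depth and spread of the day 8 drug comparison it called 68%, 98%, 98% and 100% of genes changed by 1.5, 2, 4 and 8 fold, with 9 false calls among 16337 genes. For the drug from day 0 it called 78%, 94%, 98% and 98%, with 8 false calls among 17158 genes.

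Alternatives were DESeq2 (Wald or likelihood ratio tests), RLE scaling factors, no filter on low counts, a filter of at least 1 CPM, limma voom with sample weights, a fit of only the compared groups, calls limited to a log2 fold change of at least 1 in size, and leaving out each library in turn. For the set medians they were genes changed by a log2 of at least 2, all called genes, DESeq2 size factors and a prior count of 5, and for the correlations genes with a mean log2 CPM of at least 3. A fit without day 2 imiquimod libraries 9 and 11 and the comparison of day 5 with start on day 0 were added after seeing the data. To see whether other groupings give as many calls, the libraries of each comparison were also split into mixed groups in up to 100 ways. Each split was fitted again with only those libraries. Gene coordinates were not used here, since the reference at hand is of another build than the deposited tables.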

Results

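Expression was measured in 82 libraries of mouse ear skin from 2 experiments in which 5% imiquimod cream, an agonist of TLR7, drove skin inflammation and IDOR-1117-2520, an oral inhibitor of the chemokine receptor CCR6, was given to some of the mice. The time course held 52 libraries in 9 groups: sham, imiquimod, and imiquimod with the drug, at days 2, 5 and 8. The start-day experiment held 30 libraries in 5 groups: sham, imiquimod, and imiquimod with the drug started on day 0, 3 or 5. Each group had 6 libraries except the day 5 sham group, which had 4. Depth ran from 13.1 M to 35.4 M counts in the time course and from 24.1 M to 35.5 M in the start-day experiment. A change was called at an edgeR adjusted p under 0.05, with 18780 genes tested in the time course and 18434 in the start-day experiment. Values after a ± are standard errors of log2 fold changes unless they are named as SD. The labels do not state that each library came from a separate animal, so the p values measure the spread between these samples. Genes with near-identical copies, such as the Sprr2, Stfa, Krt6, Cstdc, Serpina3, Krtap and haemoglobin families and Ugt1a6b, are uncertain as single genes because reads could be split or shared between copies. Where a group held no counts of a gene the fold change is given as a lower bound, and where it held 1 to 3 counts as a ratio with a 95% interval, and both cover counting error only.

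Imiquimod set the main axis of both experiments. The leading principal component carried 52.4% of the variance in the time course and 62.4% in the start-day experiment. Sham ears lay between -86.8 and -59.4 at day 2, between -81.1 and -76.6 at day 5 and between -77.9 and -70.0 at day 8. Imiquimod ears lay between -16.1 and 31.4 at day 2, between 64.7 and 89.4 at day 5 and between 53.8 and 67.2 at day 8. Ears with imiquimod and the drug lay below every imiquimod ear at day 5 (2.33 to 58.8) and overlapped the imiquimod ears at day 2 (-37.4 to -10.5) and day 8 (31.8 to 69.7). In the start-day experiment the sham ears lay between -121 and -112 and the imiquimod ears between 40.5 and 55.4. All 18 ears with the drug lay below every imiquimod ear there, at 7.21 to 26.5 from day 0, 20.8 to 27.1 from day 3 and 8.77 to 37.4 from day 5.

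**Figure D1:**
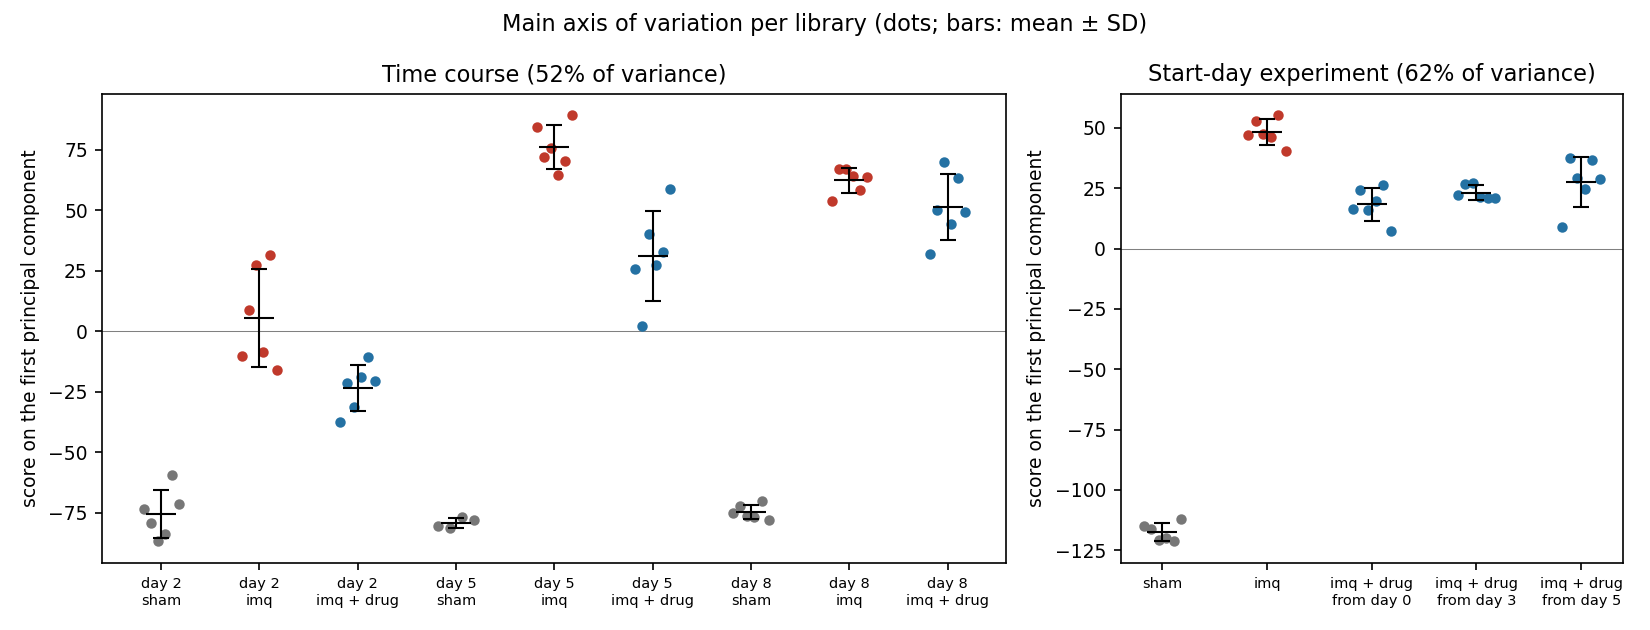
Position of each library on the leading principal component of log2 CPM, by group, for the time course (52% of variance) and the start-day experiment (62%).

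At day 2, imiquimod raised genes of keratinocyte activation, antimicrobial defence and the cell cycle and lowered genes of cartilage and nerve sheath (n = 6 imiquimod and 6 sham ears). S100a8 and S100a9, the subunits of calprotectin, rose by log2 6.21 ± 0.70 (edgeR adjusted p 3.05e-10; 361 ± 364 against 5.02 ± 6.53 CPM, mean ± SD) and 6.28 ± 0.69 (adjusted p 1.64e-10). The stress keratin Krt6a rose by 4.51 ± 0.51 (adjusted p 3.93e-10; 2413 ± 1491 against 106 ± 136 CPM, SD). Ccl20, the ligand of CCR6, rose by 3.88 ± 0.55 (adjusted p 6.97e-08; 24.6 ± 7.39 against 1.75 ± 1.93 CPM, SD), and the interferon-induced Ifit1 by 3.19 ± 0.47 (adjusted p 1.35e-07). In all, 10840 genes differed, 5486 higher and 5354 lower, or 57.7% of those tested, and 1955 of them by a log2 of at least 1.

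Some cytokines of the IL-17 axis were raised at day 2. Il17f rose by 3.09 ± 0.71 (edgeR adjusted p 0.00021), Il23a, a subunit of the cytokine that maintains IL-17-producing cells, by 2.59 ± 0.62 (adjusted p 0.000369), and Il1b by 2.44 ± 0.90 (adjusted p 0.0186). Il17a gave 16 counts against 2, a ratio of 9.98 (95% interval 2.35 to 89.5; adjusted p 0.0186), and neither Il17a nor Il1b (1.38, adjusted p 0.276) passed when imiquimod libraries 9 and 11 were left out, a fit chosen after seeing the data. Il22 (1.24 ± 0.71, adjusted p 0.135), the neutrophil chemokine Cxcl2 (1.78 ± 1.05, adjusted p 0.145) and Ccr6 (-0.10 ± 0.47, adjusted p 0.877) did not pass. Single libraries decided some of these values. Without sham library 5, which was high in both, Il1b rose by 5.22 (adjusted p 0.000219) and Cxcl2 by 5.65 (adjusted p 0.00309), and without imiquimod library 11 Il22 stood at -0.64 (adjusted p 0.463). Il1b and Il17a each lost the call without sham library 2, imiquimod library 9 or imiquimod library 11 (adjusted p 0.051 to 0.0637 for Il1b and 0.0521 to 0.134 for Il17a). The largest increases were in Sprr2g (7.11 ± 0.82), Sprr2e (6.43 ± 0.73) and Sprr2b (6.34 ± 1.15), which build the cornified envelope, in urate oxidase Uox (6.30 ± 1.05) and in S100a9. The largest decreases were in the membrane progesterone receptor Paqr7 (-3.20 ± 0.28; 23 ± 7.68 against 211 ± 42.4 CPM, SD) and in the haemoglobin genes Hbb-bt (-2.82 ± 0.34), Hba-a1 (-2.64 ± 0.29), Hbb-bs (-2.64 ± 0.33) and Hba-a2 (-2.59 ± 0.30). The largest edgeR adjusted p among these 10 genes was 7.95e-06, for Sprr2b.

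Gene lists fixed before the data were examined gave the same groups at day 2, with counts that were the same when adjusted over the list alone. All 18 cell cycle genes rose (Mcm5 1.92 ± 0.10, Mcm2 1.70 ± 0.10, Tk1 1.46 ± 0.10), as did all 17 activated keratinocyte genes (Stfa3 5.56 ± 0.44, Sprr1b 5.10 ± 0.42) and all 12 antimicrobial genes (Slpi 4.04 ± 0.29, Lcn2 2.94 ± 0.34). Among IL-1 and IL-20 family cytokines 11 of 12 rose (Il36a 3.68 ± 0.25, Il36g 1.32 ± 0.12; the list also holds the nuclear regulator Nfkbiz), and among type I interferon genes 16 of 20 rose (Irf7 3.17 ± 0.34, Bst2 2.39 ± 0.27, Isg15 3.29 ± 0.47). Camera, which compares a list with all other genes, gave these lists adjusted p 5.5e-28, 5.43e-10, 0.000245, 3.09e-06 and 0.00043 in that order. With an estimated correlation the adjusted p were 0.0695, 0.268, 0.456, 0.182 and 0.622. Cartilage genes fell in 11 of 12 cases (Col11a2 -2.09 ± 0.16, Acan -1.10 ± 0.10, Col9a1 -1.57 ± 0.15). Schwann cell genes fell in 8 of 8 (S100b -1.68 ± 0.14, Pmp22 -0.76 ± 0.07, Mbp -0.80 ± 0.09) and skeletal muscle genes in 12 of 12 (Tnnc2 -0.72 ± 0.13). Their camera adjusted p were 2.79e-08, 5.22e-06 and 0.00248, and with an estimated correlation the adjusted p were 0.177, 0.268 and 0.622.

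At day 5, S100a8, S100a9, Krt6a, Il1b, Cxcl2 and the cytokines Il17a, Il17f and Il22 were far above sham (n = 6 imiquimod and 4 sham ears). S100a8 reached 2644 ± 401 against 0.534 ± 0.386 CPM (SD; log2 12.28 ± 1.13, edgeR adjusted p 4.53e-13), S100a9 rose by 12.24 ± 1.10 (edgeR adjusted p 2.37e-13) and Krt6a by 7.47 ± 0.71 (8772 ± 1357 against 49.6 ± 3.89 CPM, SD; edgeR adjusted p 1.25e-12). Il17f rose by 5.20 ± 0.68 (edgeR adjusted p 3.24e-09), Il17a by at least 32.6-fold, and Il22, which drives epidermal thickening, by a ratio of 256 (95% interval 70.7 to 2122). Il1b rose by 9.07 ± 1.43 (edgeR adjusted p 3.26e-07; 128 ± 54.4 against 0.234 ± 0.123 CPM, SD) and Cxcl2 by 9.36 ± 1.65 (edgeR adjusted p 2.66e-06). Differences were called in 13224 genes, 6490 higher and 6734 lower, and 4954 of them were at least log2 1 in size.

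Ccr6 itself rose at day 5 (1.89 ± 0.49, edgeR adjusted p 0.000583), though only to 0.870 ± 0.350 from 0.230 ± 0.171 CPM (SD). Ccl20 rose by 4.18 ± 0.81 (edgeR adjusted p 1.29e-05), Il23a by 3.55 ± 0.68 (7.74e-06) and Ifit1 by 2.72 ± 0.53 (1.55e-05). The highest fold changes were in the stefin-like inhibitor Cstdc5 (13.03 ± 1.15, edgeR adjusted p 1.43e-13), Sprr2f (at least 1616-fold), Krt6b (12.40 ± 1.55, 1.82e-09), the acute-phase gene Saa3 (12.25 ± 1.21, 3.53e-12) and S100a8. Lowest were the suprabasal keratin Krt77 (-6.19 ± 0.46; 5.37 ± 1.01 against 393 ± 186 CPM, SD) and the serpins Serpina3b (-5.87 ± 0.34) and Serpina3j (-4.91 ± 0.44). Paqr7 (-4.65 ± 0.32) and the filaggrin relative Flg2 (-4.63 ± 0.48, edgeR adjusted p 1.17e-11, the largest of these 5) came next.

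Inflammatory lists at day 5 rose almost as a whole, with the same counts when adjusted over each list alone. Antimicrobial genes rose in 12 of 12 cases (Lcn2 5.67 ± 0.44, Slpi 5.16 ± 0.35), and acute inflammatory genes in 14 of 14. Macrophage markers rose in 14 of 14 (C1qb 2.15 ± 0.16, Cd68 1.98 ± 0.16) and neutrophil markers in 11 of 13 (Cxcr2 4.31 ± 0.35, Csf3r 6.46 ± 0.70, Mmp8 6.89 ± 0.85). Type I interferon genes rose in 18 of 20 (Oasl1 3.99 ± 0.47) and cell cycle genes in 18 of 18 (Cdk1 2.12 ± 0.15). In that order camera gave adjusted p 8.99e-05, 0.00115, 1.05e-06, 0.0134, 0.00564 and 7.19e-16. With an estimated correlation the adjusted p were 0.349, 0.444, 0.349, 0.629, 0.706 and 0.313. Cornification split, with 4 of 18 genes higher (Krt1 3.92 ± 0.21, Casp14 3.08 ± 0.15) and 13 lower (Dsg1a -1.15 ± 0.12), at a camera adjusted p of 0.497. All 11 adipocyte genes fell (Lep -2.27 ± 0.23, Adipoq -1.49 ± 0.15), as did all 12 muscle genes (Pvalb -2.69 ± 0.29, Myh2 -1.70 ± 0.17). So did 11 of 12 cartilage genes (Acan -1.29 ± 0.11) and all 8 Schwann cell genes (S100b -2.51 ± 0.15). The camera adjusted p of these lists were 8.99e-05, 0.000259, 0.000259 and 2.77e-06, and with an estimated correlation the adjusted p were 0.349, 0.531, 0.349 and 0.313. Receptor genes of gamma delta T cells fell as well (Trgc1 -2.13 ± 0.20, Trgv5 -2.93 ± 0.45, Trdv4 -2.20 ± 0.35), while the list they belong to stood at 2 higher and 7 lower of 10 (camera adjusted p 0.17).

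At day 8, the same inflammatory genes remained high, at fold changes mostly below those of day 5 (n = 6 imiquimod and 6 sham ears). For S100a8 the lower fold change came mostly from the sham level, which was low on both days, while imiquimod ears differed little. S100a8 stood at 2278 ± 224 against 1.61 ± 1.30 CPM (SD; log2 10.51 ± 0.84, edgeR adjusted p 7.23e-15), S100a9 at 10.28 ± 0.81, Krt6a at 6.27 ± 0.56 (adjusted p 1.82e-13) and Il1b at 6.96 ± 1.10 (adjusted p 4e-07). Il17f was up by 4.78 ± 0.57 (adjusted p 4.55e-10), Il22 by 4.88 ± 0.70 (adjusted p 3.51e-08), Il23a by 2.29 ± 0.54 (adjusted p 0.000217) and Il17a by a ratio of 54.1 (95% interval 14.4 to 455). Ccl20 was up by 2.62 ± 0.67 (adjusted p 0.000623), Ccr6 by 1.37 ± 0.39 (adjusted p 0.00194; 1.25 ± 0.506 against 0.485 ± 0.224 CPM, SD), Cxcl2 by 7.71 ± 1.30 (adjusted p 1.39e-06) and Ifit1 by 2.67 ± 0.45 (adjusted p 1.19e-06). EdgeR called 12793 genes, 6485 higher and 6308 lower, with 4083 at a log2 of at least 1.

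Cstdc5 (10.75 ± 0.81), S100a8, S100a9, Krt6b (10.11 ± 1.16, edgeR adjusted p 2.18e-10) and Cstdc6 (ratio 2996, 95% interval 537 to 118400) rose most at day 8. The differentiation keratins Krt24 (-7.21 ± 0.45; 2.63 ± 0.80 against 391 ± 54 CPM, SD; adjusted p 3.28e-18) and Krt77 (-6.73 ± 0.47), Serpina3b (-6.29 ± 0.35), Flg2 (-5.38 ± 0.49) and Serpinb6d (-4.73 ± 0.38) fell most. Counts over the lists were the same when adjusted over the list alone. Type I interferon genes rose in 20 of 20 cases (Mx1 3.57 ± 0.41, Oasl1 3.77 ± 0.40), as did 17 of 17 activated keratinocyte genes (Stfa3 9.52 ± 0.49). Cell cycle genes rose in 18 of 18 (Kif11 2.19 ± 0.13, Top2a 2.11 ± 0.12) and macrophage markers in 14 of 14 (Adgre1 2.27 ± 0.17). For these 4 lists camera gave adjusted p 0.000647, 1.8e-08, 3.02e-18 and 2.01e-07, and with an estimated correlation the adjusted p were 0.751, 0.335, 0.148 and 0.335. Sebaceous gland genes fell in 7 of 10 cases and rose in 1 (Scd1 -1.90 ± 0.12, Cidea -1.89 ± 0.14, Far2 -1.63 ± 0.14), and all 11 adipocyte genes (Plin4 -1.56 ± 0.11) and all 8 Schwann cell genes (Pmp22 -1.27 ± 0.07) fell. These lists had camera adjusted p of 0.00202, 0.000101 and 9.02e-09, and with an estimated correlation the adjusted p were 0.516, 0.335 and 0.148. Scart2, a scavenger receptor of IL-17-producing gamma delta T cells, rose by 3.20 ± 0.27, while Trgv5 (-4.24 ± 0.53), Trdv4 (-2.84 ± 0.35) and Trgc1 (-1.62 ± 0.19) stayed below sham.

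The size of the imiquimod effect differed among the 3 days for 6273 genes (edgeR F test). Among the 10 smallest adjusted p were the mitochondrial subunit Ndufa4l2, lower at day 2 (-0.87 ± 0.16) but higher at day 5 (1.94 ± 0.17) and day 8 (1.85 ± 0.15). The glycolytic Tpi1 rose throughout (0.39 ± 0.06, 1.35 ± 0.06 and 1.20 ± 0.06 in day order). The carboxylesterase Ces1d fell further with time (-1.03 ± 0.14, -3.37 ± 0.17 and -3.64 ± 0.16), as did Serpina3b and the hemidesmosome collagen Col17a1 (-0.22 ± 0.07, -1.17 ± 0.08 and -1.22 ± 0.07). Msi1, an RNA-binding protein of progenitor cells, climbed (1.16 ± 0.15, 2.95 ± 0.17 and 3.90 ± 0.15), and so did Purg (1.17 ± 0.16, 2.89 ± 0.17 and 3.97 ± 0.15) and the adaptor Sh3kbp1 (0.41 ± 0.06, 1.19 ± 0.07 and 1.37 ± 0.06). Scara3 turned from higher at day 2 (0.26 ± 0.07) to lower at day 8 (-0.99 ± 0.07), and the retinoic acid hydroxylase Cyp26b1 fell mainly at day 8 (-1.26 ± 0.07). Their edgeR adjusted p ran from 3.91e-13 (Ces1d) to 1.36e-11 (Col17a1). Of the inflammatory genes, S100a9 (adjusted p 0.000136), S100a8 (0.000158), Il22 (0.000618), Krt6a (0.0027), Il1b (0.00918), Cxcl2 (0.0105) and Ccr6 (0.0422) differed among days.

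**Figure D2:**
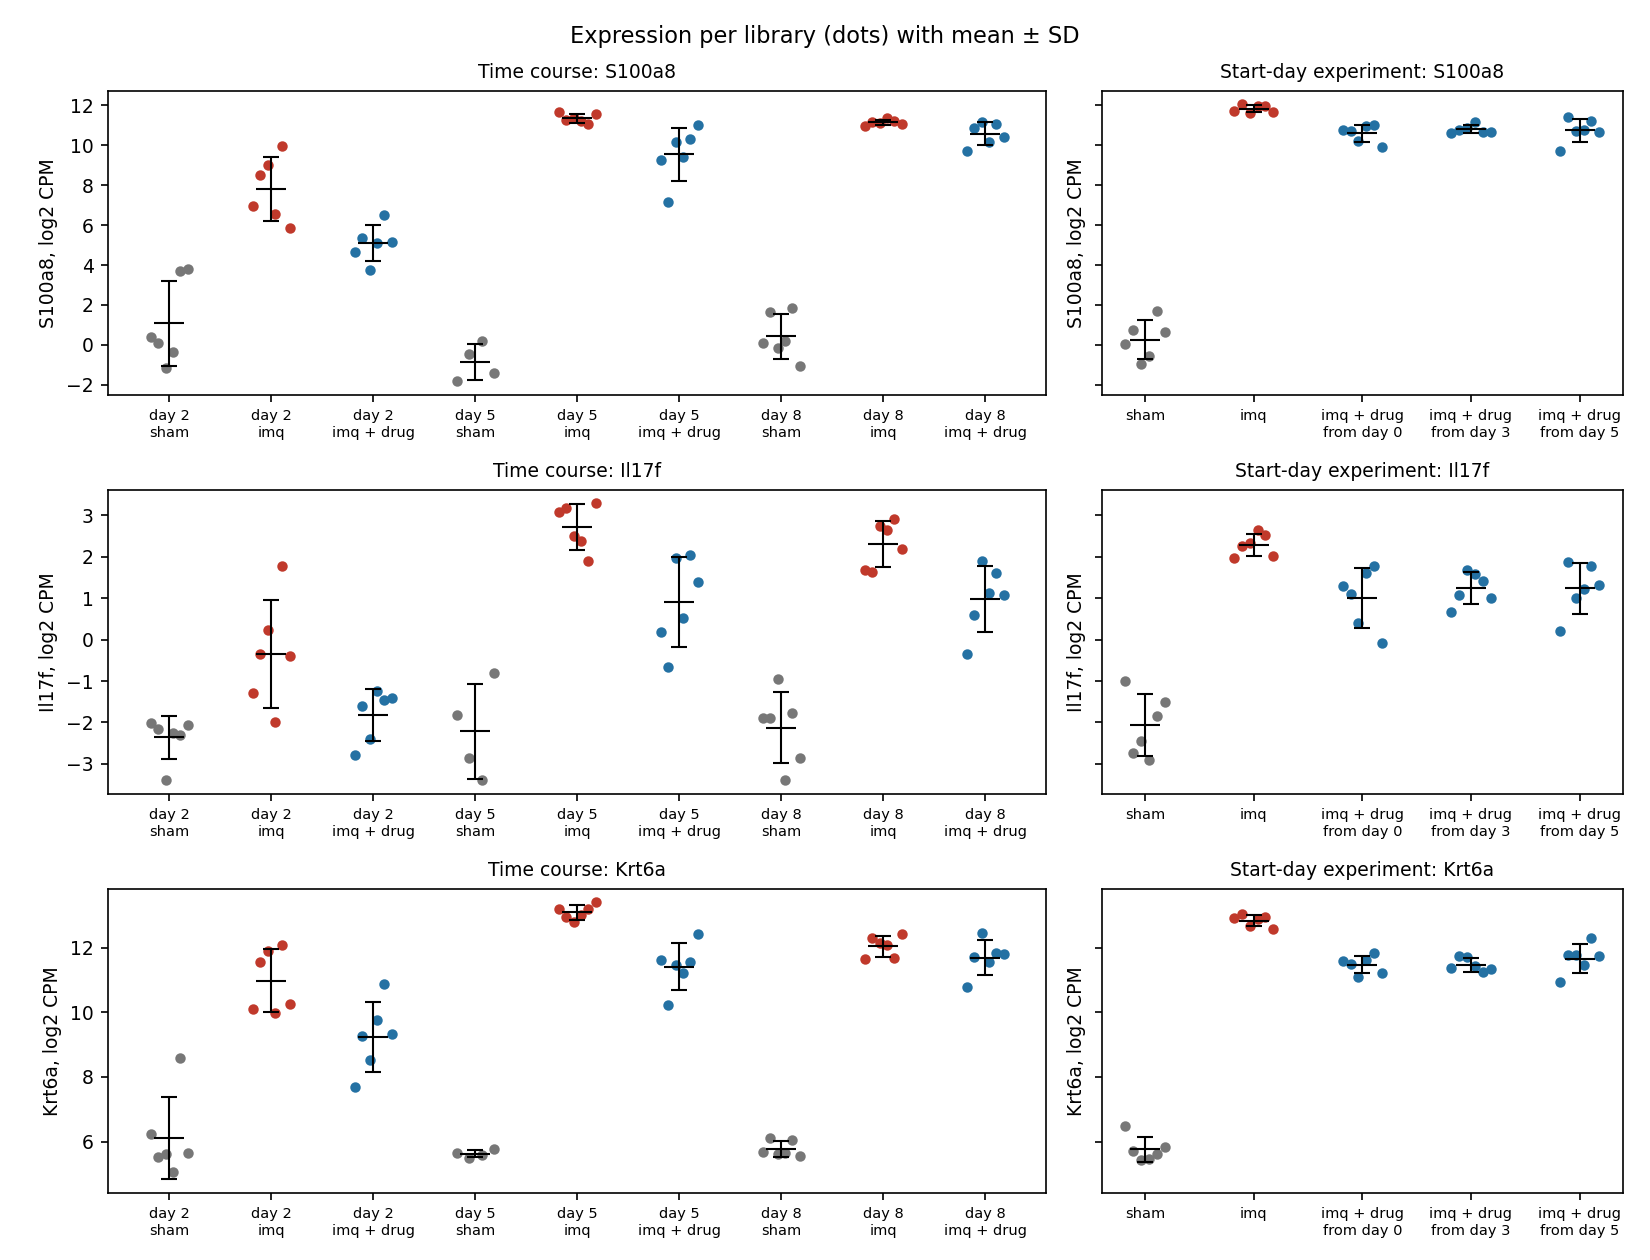
Log2 CPM of S100a8, Il17f and Krt6a in every library of both experiments, with the group mean and SD.

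At day 2, ears with the drug had less of the antimicrobial and keratinocyte activation transcripts, and of Il17f and Il22, than ears with imiquimod alone (n = 6 and 6). S100a8 fell by 3.17 ± 0.58 (edgeR adjusted p 0.000776; 40.2 ± 26.7 against 361 ± 364 CPM, SD), S100a9 fell by 3.08 ± 0.57 (adjusted p 0.000803) and Krt6a fell by 1.66 ± 0.45 (adjusted p 0.00991). Il17f fell by 2.24 ± 0.65 (adjusted p 0.0143) and Il22 fell by 2.83 ± 0.89 (adjusted p 0.023), and Il17a gave 2 counts against 16, a ratio of 0.114 (95% interval 0.0127 to 0.485; adjusted p 0.0717). Changes were called in 3100 genes, 1295 higher and 1805 lower, of which 210 were at least log2 1 in size and 177 of those lower. These calls did not hold under 2 other fits: with only the compared groups, which also changed the genes tested (16355), edgeR called 0 genes (4612 at an unadjusted p under 0.05; DESeq2 called 2284), and without imiquimod libraries 9 and 11, a fit chosen after seeing the data, it called 7, and Il17f (-1.15, adjusted p 0.465) and Il22 (-0.64, adjusted p 0.813) did not pass.

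The CCR6 ligand and receptor did not pass at day 2 (Ccl20 -0.93 ± 0.46, edgeR adjusted p 0.165; Ccr6 -1.25 ± 0.55, 0.113), nor did Il23a (-0.57 ± 0.52, 0.487), Il1b (-0.81 ± 0.78, 0.525), Cxcl2 (0.22 ± 0.88, 0.901) or Ifit1 (0.52 ± 0.39, 0.377). Without drug library 13, which was high in both, Il1b passed at -2.91 (adjusted p 0.0328) and Cxcl2 turned to -2.30 (adjusted p 0.153). Without imiquimod library 11 alone Il17f (-1.51, adjusted p 0.133) and Il22 (-0.95, 0.55) lost their calls, and Il22 also lost it without drug library 13 (0.0655) or 14 (0.0572). Il17a passed without imiquimod library 7 (0.044), 8 (0.0468) or 12 (0.0392). Highest were Paqr7 (1.89 ± 0.27, edgeR adjusted p 0.000106; 85.1 ± 67.1 against 23 ± 7.68 CPM, SD), the glucuronosyltransferase Ugt1a6b (1.07 ± 0.29, 0.00963), and the actin-bundling Pls1 (0.96 ± 0.31, 0.0254), followed by the Skint family member Skint7 (0.91 ± 0.25, 0.0101), and the potassium channel Kcnj16 (0.91 ± 0.25, 0.00906). Lowest were Sprr2b (-3.71 ± 0.84, 0.00265), Uox (-3.39 ± 0.74, 0.00206), S100a8, S100a9 and the macrophage protein Chil3 (-2.96 ± 0.72, 0.00449). Antimicrobial genes fell in 9 of 12 cases (9 over the list alone; Defb4 -2.87 ± 0.60, Lcn2 -1.23 ± 0.30). Activated keratinocyte genes fell in 13 of 17 (16 over the list alone; Sprr2d -2.08 ± 0.39, Stfa1 -2.44 ± 0.53) and cell cycle genes in 13 of 18 (17 over the list alone; Aurka -0.65 ± 0.14, Plk1 -0.62 ± 0.15). Among IL-1 and IL-20 family cytokines 5 of 12 fell (7 over the list alone), with Il19 at -5.30 ± 1.08 and Il36g at -0.48 ± 0.12, and in the IL-17 axis 2 of 11 fell (4 over the list alone). The camera adjusted p of these 5 lists were 3.69e-06, 2.66e-08, 1.64e-09, 0.00127 and 0.0299 in that order, and 0.482 for each with an estimated correlation. Neutrophil-attracting Cxcl5 (-5.03 ± 1.14, edgeR adjusted p 0.00285) and Cxcl1 (-1.31 ± 0.45, 0.0387), their receptor Cxcr2 (-1.37 ± 0.28, 0.00122) and the adhesion molecules Sele (-1.33 ± 0.26, 0.000937) and Icam1 (-0.78 ± 0.16) were lower too.

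At day 5, the drug lowered neutrophil and macrophage transcripts, Il17a and Il17f, and raised genes of the differentiated epidermis, sebaceous gland and fat (n = 6 and 6). Il17a fell by 2.11 ± 0.59 (edgeR adjusted p 0.00381), and Il17f fell by 1.62 ± 0.43 (adjusted p 0.0027). Krt6a fell by 1.55 ± 0.45 (adjusted p 0.00635; 3003 ± 1414 against 8772 ± 1357 CPM, SD). S100a8 fell by 1.42 ± 0.53 (adjusted p 0.0332; 985 ± 664 against 2644 ± 401 CPM, SD) and S100a9 fell by 1.52 ± 0.53 (adjusted p 0.0219). S100a8 lost the call in 5 of 12 fits that left out a single library (adjusted p 0.0562 to 0.0843), and S100a9 lost it without drug library 32 (0.0593). Ccl20 went the other way, up by 1.19 ± 0.48 (adjusted p 0.0469; 14.4 ± 9.59 against 6.34 ± 5.16 CPM, SD). That call was lost under DESeq2 (adjusted p 0.066) and in most fits that left out a single library (edgeR adjusted p 0.052 to 0.16). Ccr6 (-0.70 ± 0.39, adjusted p 0.163), Il22 (-0.98 ± 0.47, 0.0963), Il1b (-1.60 ± 0.67, 0.0597), Cxcl2 (-1.37 ± 0.72, 0.134), Ifit1 (-0.97 ± 0.41, 0.0563) and Il23a (0.16 ± 0.44, 0.814) did not pass. Without drug library 36, Il1b (-2.37, adjusted p 0.00697), Cxcl2 (-2.43, 0.00918) and Ifit1 (-1.25, 0.0175) passed, and Ifit1 also passed without imiquimod library 25 (0.036) or 28 (0.0279) or drug library 34 (0.0484). Calls numbered 6654, 3428 higher and 3226 lower, with 918 at a log2 of at least 1.

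The strongest rises at day 5 were in Mt4, a metallothionein of stratified epithelium (2.11 ± 0.30, edgeR adjusted p 5.81e-07; 92.9 ± 37.4 against 21.5 ± 11.8 CPM, SD), and Skint7 (2.10 ± 0.34, 3.29e-06). Close behind were neuronatin Nnat (2.10 ± 0.33, 4.13e-06), the epidermal lipoxygenase Alox12e (2.08 ± 0.32, 2.62e-06) and Krt77 (2.08 ± 0.43, 0.00018). The strongest falls were in Saa3 (-2.45 ± 0.48, 0.000105; 50.4 ± 59.7 against 275 ± 67.8 CPM, SD), and the pentraxin Ptx3 (-2.33 ± 0.42, 2.66e-05). The granulocyte growth factor receptor Csf3r (-2.19 ± 0.43, 8.84e-05), the gelatinase Mmp9 (-2.06 ± 0.29, 7.53e-07) and the aggrecanase Adamts4 (-1.95 ± 0.33, 1.15e-05) followed. Macrophage markers fell in 14 of 14 cases (14 over the list alone; Cd68 -0.86 ± 0.13, Cd163 -1.09 ± 0.18) and neutrophil markers in 12 of 13 (12; Retnlg -3.03 ± 0.58, Fpr2 -1.86 ± 0.38). Antimicrobial genes fell in 10 of 12 (11; Defb4 -1.98 ± 0.40) and type I interferon genes in 10 of 20 (11; Oas2 -1.23 ± 0.27). By camera these had adjusted p 9.72e-09, 9.28e-06, 0.000197 and 0.00027, and with an estimated correlation the adjusted p were 0.243, 0.243, 0.273 and 0.475. Fibroblast genes fell in 10 of 14 cases and rose in 1 (11 and 1 over the list alone; Pdgfra -0.89 ± 0.12, Fbn1 -0.59 ± 0.08), and endothelial genes fell in 9 of 11 (9; Selp -1.50 ± 0.22, Sele -1.44 ± 0.25). Both had low camera adjusted p, 5.99e-06 and 0.000105 (adjusted p 0.243 for both with an estimated correlation).

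Cornification genes rose in 15 of 18 cases and fell in 1 at day 5 (Krt10 1.12 ± 0.15, Krt2 1.70 ± 0.24, Lor 1.37 ± 0.24). Sebaceous gland genes rose in 9 of 10 (Scd1 1.03 ± 0.12, Far2 1.20 ± 0.14, Cidea 1.00 ± 0.13). Adipocyte genes rose in 11 of 11 (Lep 1.53 ± 0.22, Lpl 0.68 ± 0.10, Adipoq 0.94 ± 0.14) and Schwann cell genes in 8 of 8 (S100b 0.94 ± 0.14). These 4 counts were the same when adjusted over the list alone. Muscle genes rose in 8 of 12 cases (9 over the list alone; Myh2 0.87 ± 0.15) and cartilage genes in 8 of 12 (8 over the list alone; Acan 0.53 ± 0.10). The 6 lists had camera adjusted p of 2.3e-07, 1.06e-09, 1.06e-09, 9.73e-05, 0.000756 and 0.00527 in that order. With an estimated correlation the adjusted p were 0.263, 0.0968, 0.0968, 0.243, 0.415 and 0.415. In the IL-17 axis Il1r1, the receptor of IL-1 (-0.76 ± 0.09), fell with Il17a and Il17f, while Ccl20 rose and Il22, Il23a and Ccr6 did not pass. The mean of that list was 1.35 log2 CPM (SD 0.38) under imiquimod and 1.13 (SD 0.41) with the drug.

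At day 8, genes of the differentiated epidermis and the sebaceous gland stood above imiquimod alone, and no gene of the inflammatory panel passed (n = 6 and 6). Krt24 rose by 2.21 ± 0.48 (edgeR adjusted p 0.0104; 12.2 ± 7.40 against 2.63 ± 0.80 CPM, SD) and Flg2 rose by 1.80 ± 0.46 (adjusted p 0.032; 41.8 ± 16.9 against 12.1 ± 4.60 CPM, SD). Serpinb6d rose by 1.70 ± 0.40 (adjusted p 0.0213), the alcohol dehydrogenase Adh6a by 1.51 ± 0.31 (adjusted p 0.00742) and Krtap19-2 by 1.42 ± 0.38 (adjusted p 0.0395). Scart2 fell by 1.39 ± 0.24 (adjusted p 0.00249; 4.84 ± 1.32 against 12.7 ± 5.56 CPM, SD). The urotensin receptor Uts2r (-0.80 ± 0.22, 0.0474), the epithelial-homing integrin Itgae (-0.67 ± 0.16, 0.0205), the protease Adamts7 (-0.62 ± 0.14, 0.0157) and C1qtnf7 (-0.58 ± 0.13, 0.01) were also lower (edgeR adjusted p). In all 293 genes were called, 230 higher and 63 lower, with 2679 at an unadjusted p under 0.05. DESeq2 called 521 and voom with sample weights 820, and the number ran from 93 to 426 when single libraries were left out.

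The panel values at day 8 were S100a8 -0.49 ± 0.52 (edgeR adjusted p 0.737), S100a9 -0.59 ± 0.52 (0.662), and Krt6a -0.31 ± 0.44 (0.82). In the IL-17 axis they were Il17a -1.68 ± 0.61 (0.155), Il17f -1.26 ± 0.44 (0.134), Il22 -0.89 ± 0.50 (0.429) and Il23a 0.08 ± 0.46 (0.969). The remaining values were Il1b 0.46 ± 0.67 (0.82), Cxcl2 0.29 ± 0.71 (0.906), Ccl20 1.44 ± 0.51 (0.148), Ccr6 -0.59 ± 0.38 (0.509) and Ifit1 -0.04 ± 0.39 (0.98). Sebaceous gland genes rose in 6 of 10 cases (9 over the list alone), among them Cidea (0.67 ± 0.14), the wax synthase Awat2 (0.95 ± 0.21), Far2 (0.63 ± 0.14) and Dgat2l6 (0.63 ± 0.14). Their camera adjusted p was 1.85e-13, and the call held with an estimated correlation (0.0458). Cornification genes rose in 5 of 18 cases (14 over the list alone; Krt2 1.15 ± 0.23, Cdsn 0.68 ± 0.16, Hrnr 0.64 ± 0.17), at a camera adjusted p of 1.08e-14 (adjusted p 0.178 with an estimated correlation). Barrier lipid enzymes rose in 1 of 11 (6 over the list alone; Elovl4 0.39 ± 0.10), at 0.000237 (adjusted p 0.381 with an estimated correlation). Among gamma delta T cell genes Scart2 fell and the epidermal receptor Trgv5 rose (2.27 ± 0.62, edgeR adjusted p 0.0432). The antimicrobial and activated keratinocyte lists gave camera adjusted p of 0.333 and 0.804.

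The drug effect differed among days for 1500 genes (edgeR F test), or 782 to 2788 when single libraries were left out and 692 when only the compared groups were fitted. The count without both day 2 imiquimod libraries 9 and 11 is not given here. Il1rap, a shared chain of IL-1 receptors, was lower at day 5 (-0.54 ± 0.07) but not at day 2 (0.10 ± 0.07) or day 8 (-0.10 ± 0.07). Arhgap22 (0.30 ± 0.11, -0.86 ± 0.11 and -0.25 ± 0.11 in day order) and the glycolytic regulator Pfkfb3 (0.28 ± 0.13, -0.72 ± 0.13 and 0.42 ± 0.13) also turned down at day 5. Fnip2 (0.07 ± 0.07, -0.59 ± 0.07 and -0.16 ± 0.07) and the neurotrophic receptor Gfra1 (-0.20 ± 0.11, -1.12 ± 0.11 and -0.16 ± 0.12) had the same course. Faah, which degrades endocannabinoids, peaked at day 5 (0.11 ± 0.11, 1.25 ± 0.12 and 0.56 ± 0.11). Ldhb (0.27 ± 0.07, 0.87 ± 0.08 and 0.24 ± 0.08), Sox21 (0.15 ± 0.10, 0.75 ± 0.10 and -0.18 ± 0.10) and Rassf10 (0.05 ± 0.10, 0.86 ± 0.10 and 0.04 ± 0.10) did so too. Their edgeR adjusted p ran from 0.000156 (Arhgap22) to 0.000281 (Rassf10). Ccl20 (adjusted p 0.0323) and S100a8 (0.0494) also differed among days.

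Taken as sets, genes that imiquimod raised or lowered in the other experiment moved back toward sham under the drug at days 2 and 5. The 2166 raised genes had a median log2 difference of -0.28 ± 0.10 at day 2 (exact permutation p 0.00866, n = 6 and 6) and -0.40 ± 0.07 at day 5 (exact p 0.00216, the smallest possible). Of these genes 83.1% and 86.9% went in that direction, and errors of medians are jackknife standard errors. The 3135 lowered genes had medians of 0.20 ± 0.07 (exact p 0.00649) and 0.42 ± 0.08 (exact p 0.00216). Without single libraries the day 2 medians ran from -0.324 to -0.229 for raised and from 0.167 to 0.229 for lowered genes. The smallest shifts in both sets came without imiquimod library 11. Day 2 medians without both imiquimod libraries 9 and 11 are not given here, and edgeR drug calls at day 2 fell to 7 without them. The day 2 shift may therefore rest in part on these libraries. At day 8 the medians were -0.09 ± 0.07 (exact p 0.203) and 0.12 ± 0.07 (exact p 0.0563). As a share of the imiquimod effect on the same genes and day, the medians came to 29% and 31.5% at day 2, 24% and 34.5% at day 5 and 5.90% and 11.5% at day 8 for raised and lowered genes. Day 8 differed from day 5 in both sets, by 0.308 (permutation adjusted p 0.0263) and -0.289 (permutation adjusted p 0.0304). Day 8 was not shown to differ from day 2 (0.202, permutation adjusted p 0.63, and -0.069, permutation adjusted p 0.792), and these tests were not among those fixed beforehand. Shuffling days also brings the change of expression between days into the permuted values. The median imiquimod effect on raised genes was 0.965 at day 2, 1.66 at day 5 and 1.46 at day 8. The test could therefore miss a difference from day 2.

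**Figure D3:**
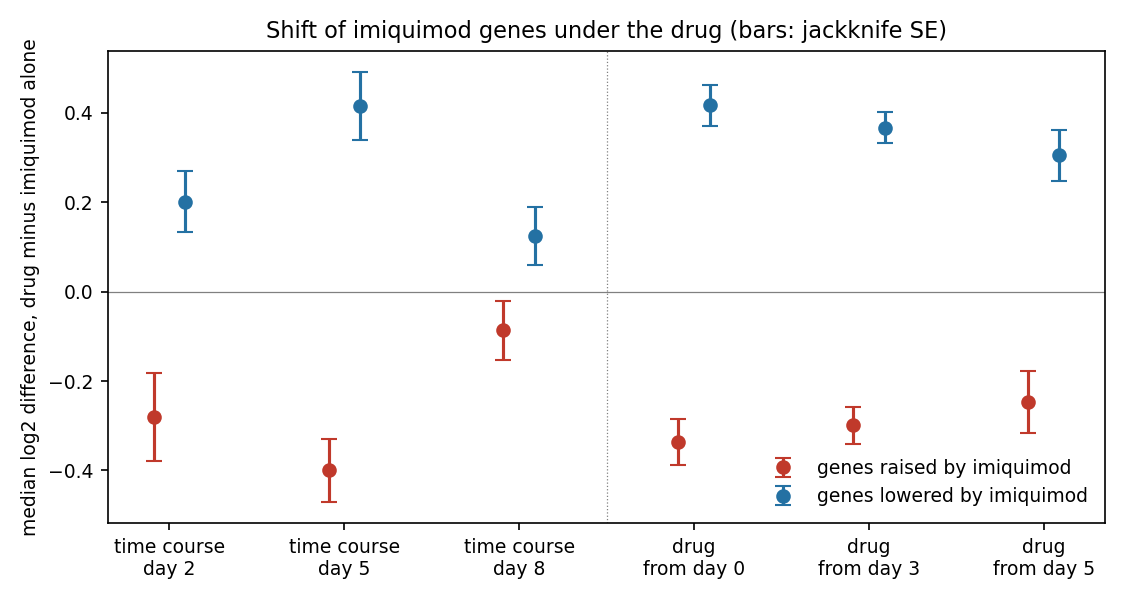
Median log2 difference between ears with and without the drug over genes raised or lowered by imiquimod in the other experiment, with jackknife standard errors, for 3 days and 3 start days.

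In the start-day experiment imiquimod raised all 12 panel genes, and more genes were called than at any day of the time course (n = 6 imiquimod and 6 sham ears). Depth was mostly greater there (24.1 M to 35.5 M counts against 13.1 M to 35.4 M). The median size of the called changes was 0.762, against 0.774 at day 5, so the higher count need not mean a larger effect. S100a8 reached 3702 ± 461 against 1.38 ± 0.98 CPM (SD; log2 11.37 ± 0.38, edgeR adjusted p 5e-20), and S100a9 rose by 12.36 ± 0.39, Krt6a by 7.04 ± 0.23, Il1b by 7.54 ± 0.50 (adjusted p 2.19e-13) and Cxcl2 by 8.73 ± 0.64. Il17a rose by 4.78 ± 0.57 (adjusted p 3.68e-09), Il17f by 4.62 ± 0.36 (adjusted p 7.88e-13), Il22 by 5.88 ± 0.42 (adjusted p 3.75e-14) and Il23a by 4.28 ± 0.38 (adjusted p 3.66e-12). Ccr6 rose by 1.72 ± 0.26 (adjusted p 2.68e-07; 1.55 ± 0.294 against 0.467 ± 0.169 CPM, SD), Ccl20 by 3.89 ± 0.51 (adjusted p 1.04e-07) and Ifit1 by 2.38 ± 0.55 (adjusted p 0.000312). EdgeR called 14393 genes, 7032 higher and 7361 lower, with 5421 at a log2 of at least 1.

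Sprr2b (12.70 ± 0.51), S100a9, Sprr2e (11.47 ± 0.44), S100a8 and the defensin Defb4 (ratio 5433, 95% interval 975 to 214640) led the increases in that experiment. Serpina3b (-7.63 ± 0.30; 0.854 ± 0.384 against 171 ± 12 CPM, SD), Krt24 (-6.36 ± 0.59, edgeR adjusted p 1.62e-10), Serpina3j (-6.03 ± 0.33), Serpinb6d (-5.53 ± 0.35) and Paqr7 (-5.21 ± 0.19) led the decreases. The counts that follow were the same when adjusted over the list alone. Activated keratinocyte genes rose in 17 of 17 cases (Stfa3 9.69 ± 0.23, Lce3c 5.90 ± 0.17) and cell cycle genes in 18 of 18 (Ccna2 2.11 ± 0.06, Top2a 2.06 ± 0.06). IL-1 and IL-20 family cytokines rose in 11 of 12 (Il36a 5.78 ± 0.13, Il36g 3.10 ± 0.11), antimicrobial genes in 12 of 12 (Slpi 6.00 ± 0.24), and barrier lipid enzymes in 10 of 11 (Cers3 2.79 ± 0.09, Pnpla1 1.73 ± 0.06). Camera returned adjusted p of 3.02e-18, 2.35e-23, 1.09e-09, 4.81e-08 and 4.05e-08, and with an estimated correlation the adjusted p were 0.0358, 0.0293, 0.0431, 0.114 and 0.114. Muscle genes fell in 12 of 12 cases (Ckm -2.84 ± 0.08, Atp2a1 -2.92 ± 0.09), Schwann cell genes in 8 of 8 (S100b -2.86 ± 0.10), cartilage genes in 10 of 12 (Acan -1.81 ± 0.06) and adipocyte genes in 11 of 11 (Adipoq -2.15 ± 0.11). Here camera gave adjusted p 1.6e-16, 1.34e-11, 6.56e-08 and 6.18e-05 (adjusted p 0.0154, 0.0154, 0.0585 and 0.196 with an estimated correlation).

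With the drug from day 0, antimicrobial, neutrophil and IL-17 axis transcripts were lower than under imiquimod alone and cornification genes were higher (n = 6 and 6). S100a8 fell by 1.20 ± 0.23 (edgeR adjusted p 0.000171; 1610 ± 441 against 3702 ± 461 CPM, SD). S100a9 fell by 1.24 ± 0.22 (adjusted p 9.33e-05) and Krt6a fell by 1.34 ± 0.18 (adjusted p 3.04e-06). Il1b fell by 1.35 ± 0.31 (adjusted p 0.00117) and Cxcl2 fell by 1.47 ± 0.34 (adjusted p 0.0012). Il17a fell by 1.39 ± 0.39 (adjusted p 0.00561), Il17f fell by 1.18 ± 0.27 (adjusted p 0.001) and Il22 fell by 1.11 ± 0.27 (adjusted p 0.00169). Ccr6 fell by 1.20 ± 0.25 (adjusted p 0.000301; 0.673 ± 0.199 against 1.55 ± 0.294 CPM, SD), while Ccl20 (0.32 ± 0.37, adjusted p 0.55), Il23a (-0.63 ± 0.27, 0.0656) and Ifit1 (-0.23 ± 0.48, 0.752) did not pass. Il23a passed without imiquimod library 12 (-0.73, adjusted p 0.0347). Calls numbered 6466, 3357 higher and 3109 lower, with 577 at a log2 of at least 1.

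From day 0 the highest fold changes were in Krt24 (2.99 ± 0.60, edgeR adjusted p 0.000304), and Hoxa11os (2.71 ± 0.40), an antisense transcript whose strand the labels do not settle. Next came Flg2 (2.46 ± 0.39, 2.58e-05; 127 ± 59.5 against 23.1 ± 11.6 CPM, SD), the cilia gene Cfap157 (2.45 ± 0.29, 6.65e-07) and Serpina3b (2.43 ± 0.36). The lowest were in Il19, a cytokine of the IL-20 family (-2.11 ± 0.32, 1.11e-05; 5.43 ± 2.75 against 23.6 ± 4.03 CPM, SD), followed by the ectonucleotidase Entpd3 (-1.91 ± 0.22, 1.68e-07), Saa3 (-1.84 ± 0.33, 9.99e-05), Cxcl5 (-1.80 ± 0.32) and Sprr2i (-1.71 ± 0.26). Antimicrobial genes fell in 11 of 12 cases (Defb4 -1.50 ± 0.18, Defb3 -1.57 ± 0.21, S100a7a -1.48 ± 0.22) and neutrophil markers in 11 of 11 (Mmp9 -1.43 ± 0.18, Csf3r -1.46 ± 0.22). Neutrophil-attracting factors fell in 6 of 6 (Csf3 -1.78 ± 0.38) and activated keratinocyte genes in 16 of 17 (Stfa2 -1.42 ± 0.18, Sprr1a -1.02 ± 0.15). Counts over each list alone were the same, with camera adjusted p 4.74e-08, 3.06e-08, 0.00119 and 8.66e-09, and with an estimated correlation the adjusted p were 0.116, 0.116, 0.184 and 0.118. In the IL-17 axis 5 of 11 genes fell and 1 rose (7 and 1 over the list alone; Il1r1 -0.51 ± 0.08; camera adjusted p 0.0339, adjusted p 0.268 with an estimated correlation). T cell markers fell in 4 of 12 cases (4 over the list alone; Icos -1.10 ± 0.17, Trbc2 -0.51 ± 0.09; camera adjusted p 0.0169, adjusted p 0.279 with an estimated correlation). The gamma delta T cell genes Scart2 (-1.16 ± 0.24), Scart1 (-1.04 ± 0.26) and Blk (-1.43 ± 0.33) fell.

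Epidermal, glandular and deep-tissue genes moved up from day 0. For the cornification list this was not a return toward sham in this experiment. Its mean was 8.08 log2 CPM in sham, 8.71 under imiquimod and 9.48, 9.62 and 9.64 with the drug from day 0, 3 and 5. The time course differed, with 8.42 in sham, 7.61 under imiquimod and 8.54 with the drug at day 5. At day 8 these means were 8.34, 7.86 and 8.54, and at day 2 they were 8.03, 8.06 and 8.42. The counts that follow are again from day 0. Cornification genes rose in 13 of 18 cases (14 over the list alone; Krt2 2.41 ± 0.30, Krt10 0.80 ± 0.13) and sebaceous gland genes in 9 of 10 (9; Far2 1.58 ± 0.14, Scd1 1.08 ± 0.13, Elovl3 1.27 ± 0.16). Muscle genes rose in 12 of 12 (12; Mylpf 0.57 ± 0.06, Atp2a1 0.77 ± 0.08) and cartilage genes in 9 of 12 (11; Cnmd 0.76 ± 0.10, Col11a2 0.45 ± 0.07). Schwann cell genes rose in 8 of 8 (8) and adipocyte genes in 8 of 11 (8; Plin4 0.75 ± 0.11). These 6 lists had camera adjusted p 8.2e-06, 3.7e-10, 8.33e-14, 9.67e-07, 4.91e-05 and 5.78e-05. With an estimated correlation the adjusted p were 0.279, 0.106, 0.0726, 0.116, 0.118 and 0.172. Endothelial genes fell in 8 of 11 cases (8 over the list alone; Selp -1.07 ± 0.16), at a camera adjusted p of 7.22e-05 (adjusted p 0.172 with an estimated correlation).

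With the drug from day 3, antimicrobial and neutrophil genes were lower than under imiquimod alone and cornification and sebaceous gland genes were higher (n = 6 and 6). Krt6a fell by 1.37 ± 0.18 (edgeR adjusted p 3.3e-06; 2848 ± 416 against 7335 ± 859 CPM, SD), S100a8 fell by 1.04 ± 0.23 (adjusted p 0.000815) and S100a9 fell by 1.13 ± 0.22 (adjusted p 0.000289). Il1b fell by 1.41 ± 0.31 (adjusted p 0.000817) and Cxcl2 fell by 1.51 ± 0.34 (adjusted p 0.000989). Il17f fell by 1.04 ± 0.27 (adjusted p 0.0029) and Il22 fell by 1.26 ± 0.27 (adjusted p 0.000547). Il17a (-0.94 ± 0.37, adjusted p 0.0483) and Ccr6 (-0.67 ± 0.24, adjusted p 0.0282) passed narrowly and lost the call in 9 and 5 of the 12 fits that left out a single library. Ccl20 (0.42 ± 0.37, 0.407), Il23a (-0.15 ± 0.26, 0.696) and Ifit1 (-0.39 ± 0.48, 0.576) did not pass. EdgeR called 6326 genes, 3310 higher and 3016 lower, with 478 at a log2 of at least 1.

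Hoxa11os (2.34 ± 0.40), Alox12e (2.30 ± 0.26, edgeR adjusted p 4.07e-07; 44.6 ± 9.87 against 9.05 ± 4.89 CPM, SD), Flg2 (2.30 ± 0.39), Krtap19-2 (2.27 ± 0.41, 0.000114) and Cfap157 (2.26 ± 0.29) rose most from day 3. Cxcl5 (-2.14 ± 0.32, 1.2e-05), Il19 (-2.01 ± 0.31), Ptx3 (-1.90 ± 0.33, 6.6e-05), Entpd3 (-1.78 ± 0.22) and the class Ib histocompatibility gene H2-Q10 (-1.76 ± 0.19, 4.36e-08) fell most. Antimicrobial genes fell in 11 of 12 cases (11 over the list alone), and neutrophil markers in 11 of 11 (11; Trem1 -1.33 ± 0.22). Neutrophil-attracting factors fell in 6 of 6 (6; Csf3 -2.43 ± 0.40), acute inflammatory genes in 11 of 14 (11) and cell cycle genes in 11 of 18 (11; Rrm2 -0.46 ± 0.09). From camera came adjusted p of 1.17e-06, 1.5e-08, 0.000117, 0.000145 and 0.00013, and with an estimated correlation the adjusted p were 0.162, 0.16, 0.162, 0.229 and 0.402. Cornification genes rose in 14 of 18 cases (15 over the list alone; Lce1c 1.15 ± 0.18), sebaceous gland genes in 9 of 10 (9; Far2 1.43 ± 0.14) and cartilage genes in 10 of 12 (10; Cnmd 0.91 ± 0.10, Col9a1 0.84 ± 0.11). Their camera adjusted p were 1.5e-08, 9.25e-11 and 2.11e-08 (adjusted p 0.229, 0.124 and 0.124 with an estimated correlation).

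With the drug from day 5, S100a8 fell by 1.01 ± 0.23 (edgeR adjusted p 0.00147), S100a9 fell by 1.06 ± 0.22 (adjusted p 0.000742) and Krt6a fell by 1.13 ± 0.18 (adjusted p 5.08e-05; n = 6 and 6). Il1b fell by 1.39 ± 0.31 (adjusted p 0.00128) and Cxcl2 fell by 1.69 ± 0.34 (adjusted p 0.000532). Il17f fell by 0.99 ± 0.27 (adjusted p 0.00562) and Il22 fell by 1.18 ± 0.27 (adjusted p 0.00142), while Il17a (-0.34 ± 0.36, 0.53), Il23a (-0.45 ± 0.26, 0.217), Ccl20 (0.59 ± 0.37, 0.254) and Ifit1 (-0.07 ± 0.47, 0.936) did not pass. Ccr6 passed at -0.67 ± 0.24 (adjusted p 0.033) and lost the call in 5 of 12 fits that left out a single library. Calls numbered 5115, 2770 higher and 2345 lower, with 361 at a log2 of at least 1. Hoxa11os (2.58 ± 0.40), Flg2 (2.55 ± 0.39), Krtap19-2 (2.32 ± 0.41, 0.000143), the suprabasal keratin Krt2 (2.21 ± 0.30, 9.5e-06; 11147 ± 6137 against 2417 ± 849 CPM, SD) and Cfap157 (2.19 ± 0.29) rose most. Cxcl2, Cxcl3 (-1.63 ± 0.39, 0.0028), Entpd3 (-1.60 ± 0.21), Il19 (-1.50 ± 0.31) and Cxcl5 (-1.49 ± 0.31) fell most.

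Antimicrobial genes from day 5 fell in 11 of 12 cases (11 over the list alone; S100a7a -1.23 ± 0.21) and neutrophil markers in 10 of 11 (11; Mmp9 -1.33 ± 0.18, Mmp8 -1.35 ± 0.25). Neutrophil-attracting factors fell in 6 of 6 (6; Ppbp -2.09 ± 0.37) and macrophage markers in 4 of 14 (4; Cd163 -0.61 ± 0.10). Camera put their adjusted p at 2.26e-08, 7.2e-09, 0.000101 and 0.0147, and with an estimated correlation the adjusted p were 0.103, 0.103, 0.166 and 0.557. Cornification genes rose in 15 of 18 cases (16 over the list alone; Krt10 0.84 ± 0.13) and sebaceous gland genes in 10 of 10 (10; Elovl3 1.05 ± 0.16). Cartilage genes rose in 9 of 12 (9; Cnmd 0.82 ± 0.10) and muscle genes in 9 of 12 (11; Ckm 0.42 ± 0.08). The 4 lists had camera adjusted p 1.32e-11, 1.17e-09, 2.15e-07 and 3.21e-06 (adjusted p 0.17, 0.103, 0.103 and 0.198 with an estimated correlation).

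Few genes were called between ears with the drug from day 5 and from day 0 (n = 6 and 6). The protease cathepsin K, Ctsk, was higher from day 5 (0.38 ± 0.06, edgeR adjusted p 0.00662; 85.3 ± 6.15 against 65.5 ± 4.79 CPM, SD). The transcription factor Klf9 (-0.48 ± 0.09; 40 ± 6.56 against 55.9 ± 8.21 CPM, SD) and the muscle RNA-binding gene Rbm24 (-0.44 ± 0.08) were lower (adjusted p 0.0366 each). EdgeR called 4 genes in all, with 2253 at an unadjusted p under 0.05, and DESeq2 called 196. The edgeR count ran from 1 to 363 when single libraries were left out, and camera called 21 of 34 lists between these groups, of which 1 held with an estimated correlation. Among panel genes the differences were Ccr6 0.52 ± 0.26 (edgeR adjusted p 0.408), Il17a 1.05 ± 0.40 (0.277), Il22 -0.07 ± 0.28 (0.952), S100a8 0.20 ± 0.22 (0.783) and Krt6a 0.22 ± 0.18 (0.673). Over the 3 start days together edgeR called 1 gene, Ctsk (adjusted p 0.0306; 1669 unadjusted), and DESeq2 called 130. The labels give a treatment day of 8, 5 or 3 for the start days 0, 3 and 5 without a separate day of harvest, and the protocol text places the first dose before day 0 for all mice. Start day and length of dosing could not be told apart.

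Imiquimod gene sets shifted toward sham for every start day. For 1867 raised genes the median log2 difference was -0.34 ± 0.05 from day 0, -0.30 ± 0.04 from day 3 and -0.25 ± 0.07 from day 5 (exact permutation p 0.00216 for each, n = 6 and 6). For 2006 lowered genes it was 0.42 ± 0.05, 0.37 ± 0.04 and 0.31 ± 0.06 (exact p 0.00216 for each). These came to 19%, 16.9% and 13.9% of the imiquimod effect for raised genes and 23.6%, 20.8% and 17.3% for lowered genes. The difference between start on day 5 and on day 0 was 0.105 for raised genes (95% interval -0.057 to 0.267; exact p 0.141) and -0.118 for lowered genes (-0.254 to 0.018; exact p 0.115).

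The imiquimod response was largely shared between the 2 experiments, which had no library in common. Over 18198 genes the log2 fold changes at day 8 and in the start-day experiment had a Pearson correlation of 0.913 (Spearman 0.890), and 5739 genes were called higher and 5535 lower in both, against 2451 and 2478 from chance. For the drug, day 8 and start on day 0 had a Pearson correlation of 0.345 (Spearman 0.417), which was 0.678 over the 10781 better expressed genes, and 232 of the 292 day 8 genes tested in both were also called in the same direction from day 0 (193 higher and 39 lower, against 42.2 and 10.7 from chance). The drug effect at day 5 and from day 0, a comparison chosen after seeing the data, had a Pearson correlation of 0.657, with 4687 of 6613 genes called in the same direction (2412 higher and 2275 lower, against 627 and 545 from chance). In a joint fit, which was not among the comparisons fixed beforehand, the drug effect from day 0 differed from that at day 8 for 671 genes by edgeR, 356 higher and 315 lower. Il1b (-1.80 ± 0.49, edgeR adjusted p 0.0373), Krt6a (-1.03 ± 0.27, 0.0332) and Cxcl2 (-1.75 ± 0.51, 0.0469) had lower drug effects from day 0 than at day 8, where none of them passed. The other panel genes were not called in this test. Among them were Il17a (0.30 ± 0.62, edgeR adjusted p 0.849), Il17f (0.09 ± 0.46, 0.951), Il22 (-0.22 ± 0.49, 0.864) and S100a8 (-0.71 ± 0.33, 0.231). The imiquimod effect differed between experiments for 4481 genes.

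**Figure D4:**
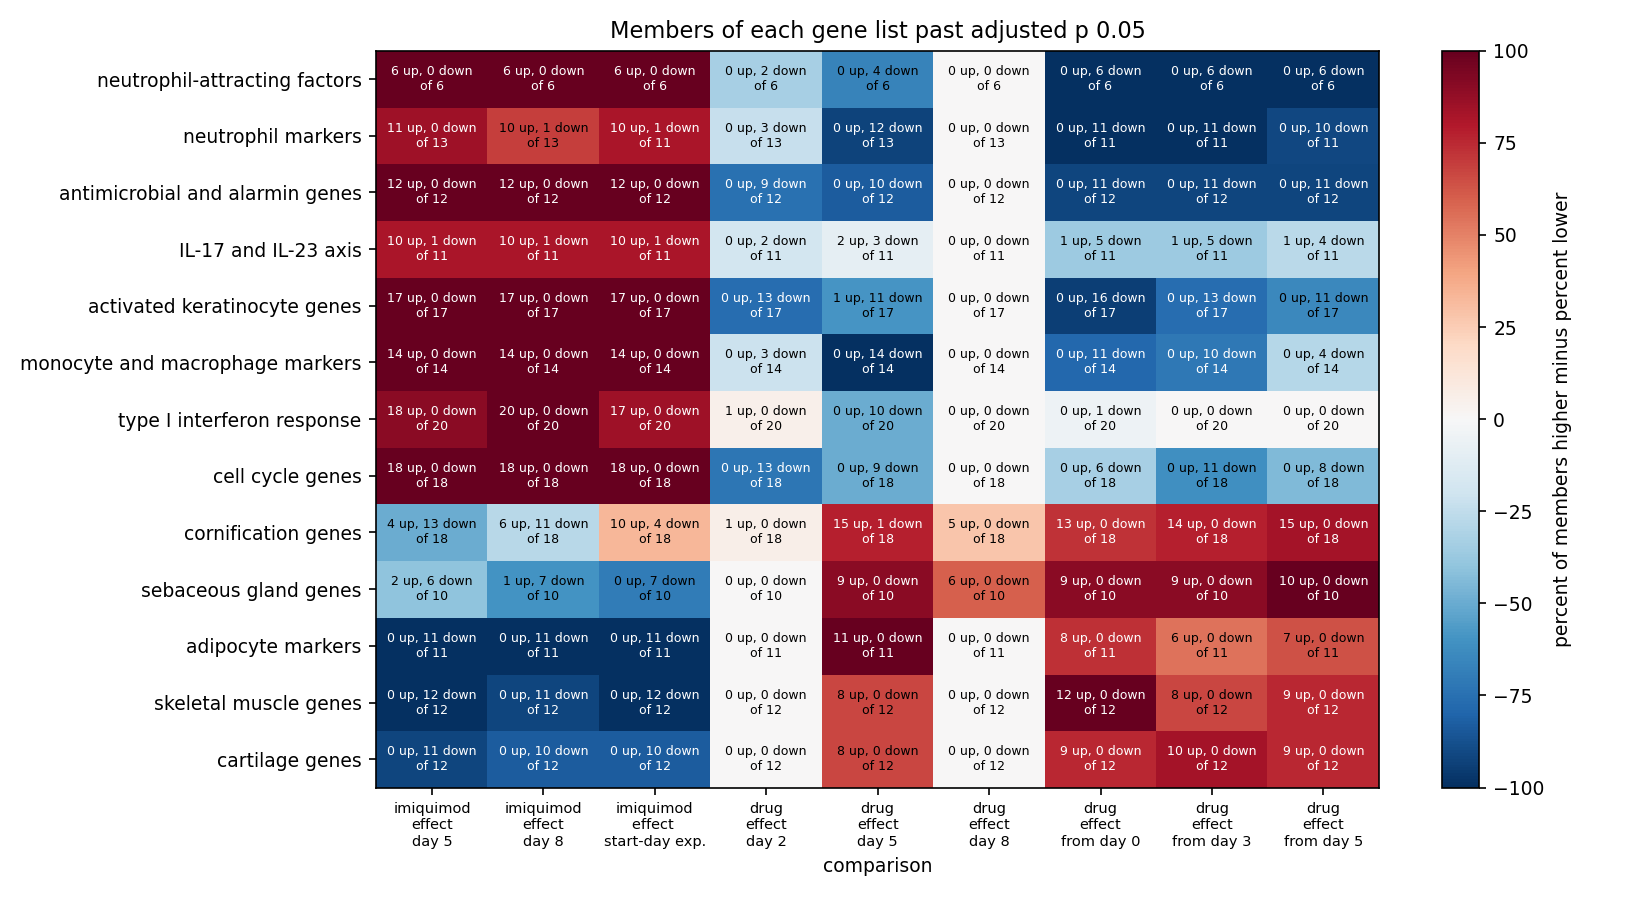
Members of 13 gene lists called higher or lower in each of 9 comparisons, for imiquimod against sham and for the drug against imiquimod alone.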

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

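In this part the tests of explanations were chosen after seeing the results, except the thinning of reads and the splits of libraries (the splits for imiquimod at days 2 and 5 were run before their prediction was written), and the day differences of set medians and the joint fit were added to the F tests fixed beforehand.

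A library lay far from the others of its group in 17 of 210 combinations of a group and a measure, where about 10.5 would be by chance. In depth these were day 2 sham library 2 (35.363 M counts, others 16.1 to 19.8) and day 8 sham library 39 (30.627 M, others 19.4 to 21.8). Library 13 of the drug from day 5 had 12.844% of its counts in the top 10 genes (others 10.5 to 11.3). In log2 CPM, day 2 sham library 5 was high in Il1b (4.04), Krt6a (8.579) and Cxcl2 (3.223) and low in Il22 (-3.386), and day 2 sham library 3 was high in Il17a (-2.342) and low in Il17f (-3.386). Day 2 library 13 with the drug was high in Il1b (5.387) and Cxcl2 (4.9) and low in Ccl20 (2.206). Single genes stood apart in day 5 library 32 with the drug (Il17a -3.386), day 8 imiquimod library 44 (Il1b 5.112), day 8 library 52 with the drug (Ccr6 -1.782), imiquimod library 12 of the start-day experiment (Ccl20 1.66) and library 16 of the drug from day 5 (Il23a 0.469). The -3.386 values are those of a count of 0.

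Effects differed between groups in these tests. Over the 3 days, 6273 genes differed in their imiquimod effect and 1500 in their drug effect (edgeR F tests). The imiquimod effect differed among days for S100a9 (edgeR adjusted p 0.000136), S100a8 (0.000158), Il22 (0.000618), Krt6a (0.0027), Il1b (0.00918), Cxcl2 (0.0105) and Ccr6 (0.0422), and the drug effect for Ccl20 (0.0323) and S100a8 (0.0494). The drug shift of imiquimod genes differed between day 8 and day 5 by 0.308 for raised and -0.289 for lowered genes. Between experiments, 671 genes differed in the drug effect and 4481 in the imiquimod effect, with drug effects further down from day 0 than at day 8 for Il1b (-1.798), Cxcl2 (-1.751) and Krt6a (-1.031). The other panel genes, Il17a, Il17f and Il22 among them, were not called for a difference in the drug effect between experiments.

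The drug comparison at day 8 gave 293 calls, against 6654 at day 5 and 6466 from day 0. Lower read depth was argued against by thinning the libraries of the comparison from day 0 to the day 8 depth (17.4 M and 21.8 M), which gave 5599 calls against 6096 at full depth with the same libraries. A larger spread with an unchanged effect was argued against by the slope of the day 8 differences on those from day 0. It was 0.302 (SE 0.106) over 6443 genes, against 0.863 ± 0.161 at day 5. The day 2 slope was 0.368 ± 0.136, so a low slope was not particular to day 8. The genes were chosen by their calls from day 0, which can lower each slope. A weaker imiquimod response was argued against for raised genes by the share of it that the drug took away, 5.90% at day 8 and 19% from day 0. The median imiquimod effects were 1.46 and 1.77. These shares came from different sets (2166 and 1867 genes), and the error of the share from day 0 was left out. For lowered genes the shares were 11.5% and 23.6%, and they were not tested in this way. A smaller drug effect at day 8 in that experiment may remain, and its cause stays open.

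The drug calls at day 2 fell from 3100 to 7 (edgeR) without imiquimod libraries 9 and 11, whose scores on the main component were 27.3 and 31.4 while the other day 2 imiquimod libraries lay between -16.1 and 8.61. That they were mislabelled imiquimod libraries of a later day without the drug was argued against by the higher score, 31.4, against a lowest of 53.8 at days 5 and 8. Later libraries with the drug reached such scores (2.33 to 69.7), but on component 2 the pair lay at -30.5 and -28.2, near the other day 2 imiquimod libraries (-33.3 to -28.9) and narrowly below the limit of -28.0 set by the lowest later library with the drug, -17.8, less 1 SD. Shallow sequencing was argued against for library 9 (20.9 M counts, median of the others 17.5 M) and for library 11 by its main component score over 6129 abundant genes, 15.5, where the others reached 7.20 (SD 4.80). A faster response in these 2 ears could remain, and no biological explanation was tested.

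Muscle and cartilage genes fell together under imiquimod. A smaller share of deep tissue in the punch, lowering all its genes alike, was argued against at day 2, where cartilage fell by 1.36 and muscle fell by 0.754 (difference -0.604, exact p 0.00216), and in the start-day experiment (difference 1.02, exact p 0.00216), but not at days 5 (0.174, exact p 0.467) and 8 (0.162, exact p 0.335). The difference of 1.02 also argued against a scaling shift moving all genes by 1 amount as the whole cause. A dilution by thickened or infiltrated skin that differs by tissue layer could still contribute.

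The libraries were also split into mixed groups to count the calls under other groupings. Each fit held only the compared libraries, and the true grouping is among the 100 splits counted. Treated libraries stay in every split, so the splits do not show how many calls arise without the treatment. The true grouping alone reached its count (1 of 100) for imiquimod at day 2 (10142 calls, highest other 4313), day 5 (12574, 2605), day 8 (12061, 2667) and in the start-day experiment (14074, 4760), and for the drug at day 5 (6005, 5346), day 8 (365, 162), from day 0 (6096, 971), day 3 (6197, 4028) and day 5 (4456, 23). It also did so for the drug from day 5 against day 0 (6, 4) and for the tests among days (imiquimod 6394, 2379, and drug 692, 3). The median over the other splits was 0 throughout, which can come from the wider spread within mixed groups. Whether the single splits with many calls exchanged few libraries or reflect other structure was not tested. For the drug at day 2 (edgeR 0 calls, highest other 1; 4612 unadjusted, DESeq2 2284) and for the test over start days (edgeR 0, highest other 2; DESeq2 with all groups 130), the true grouping had no call, so all 100 splits reached it by necessity and the splits decided nothing.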

How the results depend on the processing

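Alternatives were fixed before the data were examined except the fit without day 2 imiquimod libraries 9 and 11, chosen after seeing the result. No paired analysis was possible because the compared groups share no replicate numbers.

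Imiquimod counts stayed within 1.5 times under every other tool, filter, scaling and left-out library (10181 to 10847 genes at day 2, 12760 to 13092 at day 5, 12472 to 12647 at day 8 and 14200 to 14369 in the start-day experiment when single libraries were left out), as did the drug at day 5 (5354 to 7150) and from day 0 (5759 to 6582), day 3 (5476 to 6425) and day 5 (4154 to 5270). Requiring a log2 fold change of at least 1 left 1955, 4954 and 4083 imiquimod calls at days 2, 5 and 8 and 5421 in the start-day experiment, 210, 918 and 39 drug calls, 577, 478 and 361 by start day, and 0 of the 4 edgeR calls between start days (2253 unadjusted). That filter alone explains these falls. The causes of the changes below were not tested.

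The drug comparison at day 2 went from 3100 edgeR calls to 0 with only the compared groups (4612 unadjusted, DESeq2 2284) and 7 without both libraries 9 and 11. Leaving out single libraries gave 1416 (imiquimod 9) to 3889, with 1740 (imiquimod 11) and 1766 (drug 13). Without both, S100a8 was -2.02 (edgeR adjusted p 0.0853), 1 of 58 named calls was kept (Paqr7 1.63), all 58 kept their direction, and the Il17a imiquimod effect turned to -0.108 (adjusted p 0.963). At day 8 the drug gave 521 calls with DESeq2, 820 with voom and 147 with no filter, and 93 (drug 54) to 426 when single libraries were left out, with falls of over 1.5 times also without imiquimod 45 (134), 46 (137), 47 (165), 48 (111) and 49 (124) and drug 52 (98) and 56 (172). The drug effect differed among days for 703 genes with no filter and 2488 with voom, and for 782 (imiquimod 30) to 2788 (drug 36) without single libraries, with 927 (imiquimod 25), 812 (drug 32), 2507 (drug 51) and 869 (drug 53). Drug from day 5 against day 0 gave 196 calls with DESeq2, 41 with voom, 16 with no filter and 1 (library 14) to 363 (library 13) without single libraries. Over the start days the counts were 130 with DESeq2, 27 with voom, 6 with no filter, 2 with RLE, 2 with the CPM filter, and 0 to 109 without single libraries (edgeR; 1669 unadjusted in the full fit).

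The day 8 shift of lowered genes was 0.237 (exact p 0.0325) for genes changed by a log2 of at least 2, and ran from 0.081 to 0.156 without single libraries, past the threshold without drug 53 (0.156), drug 55 (0.145) or imiquimod 48 (0.142). Raised genes ran from -0.125 (without drug 53, past the threshold) to -0.045. The drug correlation between experiments was 0.678 over better expressed genes.

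Lists called by camera at the preset correlation, with an estimated one and by fry were 14, 0 and 22 for imiquimod at day 2, 13, 0 and 25 at day 5, 13, 0 and 25 at day 8 and 16, 5 and 28 in the start-day experiment. For the drug they were 16, 0 and 10 at day 2, 18, 0 and 20 at day 5, 11, 1 and 2 at day 8, 19, 0 and 24 from day 0, 16, 0 and 21 from day 3, 14, 0 and 17 from day 5, and 21, 1 and 2 between start days 5 and 0. Where camera with an estimated correlation called 0 lists, 5, 3, 3, 1, 4, 9, 6 and 7 had an unadjusted p under 0.05 (imiquimod days 2, 5, 8, then drug days 2, 5, from day 0, 3, 5).

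Of 7185 values of named genes under the other settings fixed beforehand, 6969 kept direction and side of the threshold. Of the rest, 200 became weaker, 9 stronger, 7 changed sign without a call and 0 reversed a call. Of 14224 values without a library, 13703 kept direction and side, 479 became weaker, 12 stronger, 30 changed sign without a call and 0 reversed a call (edgeR). The fit without both libraries 9 and 11 is not counted in these values. In that fit 1 of 58 named drug calls and 127 of 141 named imiquimod calls at day 2 were kept, and the imiquimod call of Il17a reversed in sign. The Ccl20 rise with the drug at day 5 was lost under DESeq2 (adjusted p 0.066), RLE (0.0502), only the compared groups (0.151) and no filter. It was also lost in 9 of 12 fits without a library (edgeR adjusted p 0.052 to 0.16). The lowest log2 fold change in those fits was 0.895, without drug library 34. Depth of 13.1 M counts and up limits Il17a, Il22 and Ccr6, whose sham values rest on few counts.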

Other observations

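The set difference and the test of a hypothesis in this part were chosen after seeing the results.

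Regulatory T cell genes rose under imiquimod in 5 of 8 cases and fell in 1 at day 8 (5 and 1 over the list alone; Foxp3 3.05 ± 0.43, Ctla4 2.66 ± 0.39, Il2ra 2.31 ± 0.28; camera adjusted p 0.421), and Foxp3 rose by 4.18 ± 0.26 in the start-day experiment. With the drug from day 0, 4 of 8 fell and 1 rose (4 and 1 over the list alone; Foxp3 -1.19 ± 0.21, Ctla4 -1.08 ± 0.20; camera adjusted p 0.0281, adjusted p 0.201 with an estimated correlation), and at day 5 Foxp3 (-1.67 ± 0.41), Ctla4 (-1.47 ± 0.37) and Il2ra (-1.16 ± 0.25) were lower. The granule protease Gzmb rose at day 5 of imiquimod (3.86 ± 0.53) while perforin, Prf1, fell (-1.66 ± 0.24), and Gzmb fell with the drug from day 0 (-1.46 ± 0.19). Genes of type 2 immunity fell with the drug at day 5 in 5 of 7 cases and rose in 1 (5 and 1 over the list alone; Arg1 -1.17 ± 0.21, Il1rl1 -1.16 ± 0.27, Chil3 -1.57 ± 0.48; camera adjusted p 0.0411, adjusted p 0.243 with an estimated correlation).

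In the start-day experiment the Langerhans cell lectin Cd207 fell under imiquimod (-2.24 ± 0.13) and rose with the drug from day 0 (0.88 ± 0.13), while the migration genes Ccr7 (2.34 ± 0.23) and Fscn1 (2.03 ± 0.11) rose under imiquimod. Among genes of the mast cell list Kit fell (-1.04 ± 0.07) and the histamine enzyme Hdc rose (2.85 ± 0.25), and Hdc fell with the drug from day 0 (-1.19 ± 0.23). In the time course the mean of that list was higher under imiquimod than in sham (3.21 against 2.79 log2 CPM at day 2, 3.62 against 3.07 at day 5 and 3.54 against 3.25 at day 8). In the start-day experiment it stayed flat, at 3.71 log2 CPM in sham and 3.70 under imiquimod. Among hair follicle genes Lef1 (-1.61 ± 0.12), Msx2 (-1.42 ± 0.13) and Hoxc13 (-1.57 ± 0.18) fell and Tchh rose (1.56 ± 0.10), and Hoxc13 rose with the drug from day 0 (1.17 ± 0.18). Red blood cell genes, 5 of 6 of which fell under imiquimod at day 2 (5 over the list alone), rose in 6 of 6 at day 5 (6 over the list alone; camera adjusted p 0.117). Mitochondrially encoded genes rose with the drug at day 5 in 8 of 13 cases (9 over the list alone; camera adjusted p 0.0017, adjusted p 0.415 with an estimated correlation).

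Transcripts of IL-17-type gamma delta T cells (Scart2, Scart1, Blk, Il23r, Il17a, Il17f) changed by -1.12 in mean log2 CPM with the drug from day 0. Receptor genes of gamma delta T cells (Trdv4, Trgv5, Trgc1), which need not mark a single type of these cells, changed by 0.50, a difference of -1.62 (n = 6 and 6). These genes were put into sets after most of their changes had been seen, so the difference restates those changes and does not test a hypothesis.

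A hypothesis was that the drug effect at day 8 runs against the imiquimod effect of the other experiment across genes. Spearman rho was -0.294 over 18198 genes (exact p 0.271), which left it undecided, while 159 of 229 genes raised at day 8 were lowered by imiquimod there (69.4%, against 40.4% of all genes).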
